A study of Mus musculus with 90 samples.

How the data were processed

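Nuclear RNA was sequenced from the nucleus accumbens of adult mice that carried a Cre-dependent Sun1-GFP tag of the nuclear envelope together with Pvalb-IRES-Cre or Sst-IRES-Cre. Pvalb and Sst mark 2 classes of GABAergic interneuron, called PV and SST here. Per the labels' protocols, the nucleus accumbens of both sides of a single mouse was homogenised, nuclei were collected from an iodixanol gradient, and tagged nuclei were pulled down with an anti-GFP antibody on magnetic beads (the bound fraction). The supernatant was kept as the unbound fraction. Mice received saline or amphetamine at 3 mg/kg and were sampled 35 min or 3 h after 1 dose, or, for PV mice, 24 h after the last of 6 days of dosing. The term PV35min stands for the PV mice at 35 min, and SST35min, PV3h, SST3h and PV24h are formed in the same way.

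The authors deposited 5 tables of raw read counts per gene, 1 for each cross and time, with 28701 gene rows and 1 column per library, 84 libraries in all. Per the submitters' processing notes, reads were handled with Trimmomatic 0.38, STAR, HTSeq, DESeq2, Cufflinks and Cuffdiff 2.2.1 on the mm10 build. The notes give no role or order for these tools, and the filter that the table names speak of is not stated. No label gives the strandedness of the counting, so a gene and an antisense or overlapping partner may share reads, and genes with near-identical copies are uncertain. That holds for the mitochondrially encoded genes, which have nuclear copies. In every count file the symbols of 26 rows had been turned into dates by a spreadsheet and were kept as separate rows under those names. The symbols of 28451 of the 28701 rows were found in the GENCODE M21 annotation of GRCm38 (mm10), from which all positions are given, 1-based, and all 115 genes checked for a position had one. Another 6 samples, ribosome-tag pulldowns and input from mice with wild-type or Ser421Ala Mecp2, came with no file of values and were not analysed here.

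Total counts ran from 15712205 to 48829934 per library. All intervals given cover counting or sampling error only. Each of the 42 mice gave 1 bound and 1 unbound library. Pairing was checked by correlating log2 CPM (counts scaled to a common library size) of the libraries after centring each gene within its group. The median correlation between the bound and the unbound library of a mouse was 0.242 in PV35min, 0.217 in SST35min, 0.195 in PV3h, 0.36 in SST3h and 0.207 in PV24h. A saline and an amphetamine library with the same isolation number did not all correlate: their correlations ran from -0.018 to 0.219 in the unbound fraction of PV35min and from 0.063 to 0.745 in the bound fraction of PV3h. The bound and unbound libraries were therefore read as pairs by animal, and isolation number as a batch label. The main fits used neither as a term, so their standard errors and p-values ignore the pairing. The mouse or the isolation number entered as a block only in an alternative fit. The sex-linked genes gave the same sex for both libraries of all 42 mice. No 2 libraries of a group were copies of each other, over 140 pairs checked.

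Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1: filterByExpr with a minimum count of 10, TMM normalisation, and the robust quasi-likelihood F-test, which is 2-sided. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Fold changes are log2 with their standard error (SE), and CPM values carry the standard deviation (SD). The comparisons were bound against unbound nuclei in saline mice (5), amphetamine against saline within each fraction (10), the difference between the bound and the unbound amphetamine effect (5), and the difference between the PV and the SST bound effect at 35 min and at 3 h (2). The comparisons, lists, rule for named genes and other settings listed first below were fixed before the data were examined.

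Of 27 gene lists, 25 were tested with edgeR's camera at a preset correlation of 0.01, adjusted over the lists within a comparison. The sex-linked list served for the sex check, and the blood list had too few genes above the filter. Tests with an estimated correlation and with fry were alternatives. The lists held immediate-early genes, delayed activity-response genes, feedback regulators of MAP kinase signalling, glucocorticoid-response genes, circadian clock genes, heat-shock genes, neuropeptides, voltage-gated potassium channels, ionotropic glutamate receptors, GABA-A receptors, dopamine and cAMP signalling genes, chromatin regulators and mitochondrially encoded genes. The others were markers of PV, SST and cholinergic interneurons, of medium spiny neurons (MSNs) in general and of their D1 and D2 types, and of glutamatergic neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia and vascular cells. Calls within a list were also counted with p-values adjusted over the list alone. A list's level in a library is the mean log2 CPM of its members, with a prior count of 2. It was normalised over the libraries of a comparison for tests and group means, and over all libraries of a table for the figures, the terms in a fit, the correlations with a level, the changes predicted from it and the libraries that stood apart, so a library can have 2 slightly different values. These levels were compared by 2-sided exact permutation tests for 4 lists, 40 tests in all, chosen after the gene results were seen.

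For amphetamine comparisons, the rule named up to 12 genes higher and 12 lower with the smallest p among those called, up to 4 members of each list with the smallest p, and always Fos, Fosb, Junb, Npas4, Arc, Egr1, Nr4a1 and Fkbp5. Predicted genes and the sex-linked list were left out. For bound against unbound nuclei it named Pvalb, Sst, up to 4 members of each list, and the 10 largest called changes each way with at least 10 CPM. For differences between effects it named up to 10 called genes each way and the fixed 8.

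The other settings chosen beforehand were RLE normalisation, DESeq2 1.42.0, no filter on low counts, the mouse or the isolation number as a block, all 4 groups of a table in 1 fit, a term for sex, leaving out each replicate in turn, and the amphetamine-treated mice for bound against unbound nuclei. Added after seeing the data were the vascular list's level as a term in the bound fractions, the glutamatergic list's level as a term in unbound PV3h, leaving out isolation 4 of SST3h, and leaving out the PV24h mouse with the highest mitochondrial share. The scripts were tested on simulated counts with 200 changed genes. For a log2 change of 2, the amphetamine comparisons recovered 87.6% of them in bound PV35min, 85.7% in bound SST35min, 88.9% in bound PV3h, 89.8% in bound SST3h and 93.8% in bound PV24h. For a log2 change of 1 the shares were 58.6%, 48.5%, 42.7%, 63% and 48.5%. False calls in these simulations were 5 of 148, 15 of 147, 6 of 135, 14 of 165 and 4 of 141, in the same order. The simulated genes varied independently, without the cell content that genes of a real library share, so these shares may not carry over to the real libraries.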

Results

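The series asked how amphetamine, which raises extracellular dopamine, changes gene expression in PV and SST interneurons of the nucleus accumbens and in the cells around them. It held 84 nuclear RNA-seq libraries from 42 mice. In each table the 4 groups were bound and unbound nuclei after saline and after amphetamine, with 5 mice per treatment in PV35min, 3 in SST35min, 4 in PV3h, 4 in SST3h and 5 in PV24h. Total counts per library were 15712205 to 40433217 in PV35min, 17289181 to 24508133 in SST35min, 17663217 to 27723428 in PV3h, 25996029 to 43104126 in SST3h and 20460950 to 48829934 in PV24h. The mice of PV35min, SST35min and SST3h were all male by their sex-linked genes, while each PV3h treatment held 1 female and 3 males and each PV24h treatment 2 females and 3 males.

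Bound PV nuclei were compared with unbound nuclei of the same saline mice to see which cells the pulldown held. Pvalb, the calcium-binding protein that names the class (chromosome 15, 78191114 to 78206400), was higher in bound nuclei by a log2 fold change of 5.83 ± 0.3 (SE, n = 5) in PV35min, 4.53 ± 0.45 (n = 4) in PV3h and 4.26 ± 0.43 (n = 5) in PV24h. In PV35min its level was 81.2 ± 25.5 CPM (SD) in bound and 1.34 ± 0.52 CPM in unbound nuclei. Of the PV markers tested, 14 of 14 were called higher in PV35min, 10 of 14 in PV3h and 11 of 15 in PV24h, and their medians were 1.7, 0.92 and 1.21. Sst was lower in bound nuclei in PV35min (-1.33 ± 0.37) and PV24h (-0.83 ± 0.23) and was not called in PV3h (-0.19 ± 0.36). The SST markers as a list went both ways in PV35min, with 7 of 14 called higher and 4 lower. Their median was 0.535 (adjusted p = 0.876 with an estimated correlation), and Lhx6 and Sox6, among those higher, are on the PV list too.

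Genes of MSNs and oligodendrocytes were lower in bound PV nuclei. Every tested MSN marker had a negative fold change, with medians of -1.88, -1.21 and -0.89 in PV35min, PV3h and PV24h and 13 of 14 called lower in each. Oligodendrocyte markers had medians of -2.88, -2.18 and -1.7, and the myelin genes Mobp (-3.89 ± 0.25, -2.85 ± 0.25 and -2.22 ± 0.31) and Opalin (-4.13 ± 0.18, -3.18 ± 0.21 and -2.17 ± 0.36) were among the largest decreases. Astrocyte markers did not follow them, with medians of -0.33, 0.4 and 0.65, 4, 5 and 10 of 14 called higher and 2, 1 and 0 called lower. Vascular markers were higher: all 15 were called higher in each PV table, with medians of 4.02, 5.23 and 4.94. Flt1, a receptor of endothelial cells, was higher by 4.22 ± 0.42, 5.23 ± 0.62 and 4.99 ± 0.35, and Acta2, the actin of smooth muscle, by 5.7 ± 0.68 in PV35min and 7.02 ± 0.49 in PV24h.

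The edgeR test called 3916 genes higher and 3695 lower of 15053 in PV35min, 3146 higher and 2932 lower of 15477 in PV3h, and 3050 higher and 2346 lower of 16008 in PV24h. Camera called the PV, MSN, oligodendrocyte and vascular lists in all 3 tables at the preset correlation. With an estimated correlation, PV35min kept the MSN list and the oligodendrocyte list (adjusted p = 0.0282 for both). The other adjusted p-values with an estimated correlation were 0.0681, 0.0966 and 0.482 for the PV list, 0.252, 0.179 and 0.092 for the vascular list, 0.132 and 0.482 for the MSN list in PV3h and PV24h, and 0.0966 and 0.262 for the oligodendrocyte list there. In PV3h the total fell from 6078 to 3810, 3504 or 3572 when saline replicate 1, 2 or 4 was left out.

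**Figure D1:**
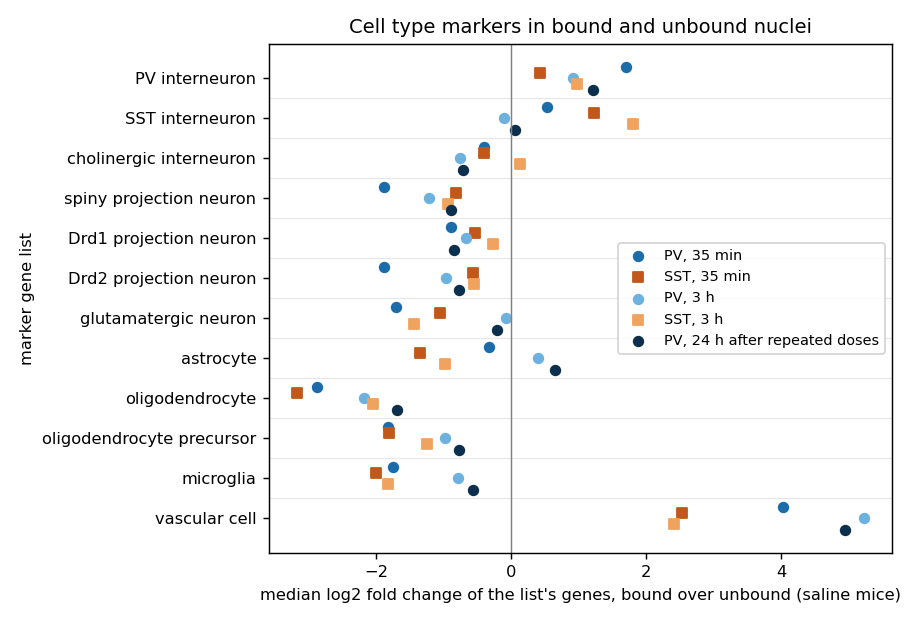
Median log2 fold change of each list of cell type markers in bound over unbound nuclei of saline mice, 1 point per list and table, with a line at 0 for no difference. PV markers lie above 0 in all 5 tables, MSN and oligodendrocyte markers below 0 in all 5, and vascular markers between 2.42 and 5.23.

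Bound SST nuclei held the genes that define SST interneurons. Sst (chromosome 16, 23889573 to 23890958), the gene of the peptide somatostatin, was higher in bound nuclei by 4.4 ± 0.15 (SE, n = 3) in SST35min and 4.85 ± 0.15 (n = 4) in SST3h, where its level was 233 ± 39.6 CPM (SD) in bound and 8.14 ± 1.08 CPM in unbound nuclei. Higher with it were Npy, a peptide of the same neurons (4.52 ± 0.26 and 4.54 ± 0.18), Nos1, their nitric oxide synthase (3.32 ± 0.15 and 3 ± 0.23), and Chodl (2.96 ± 0.24 and 3 ± 0.38). Of 15 SST markers, 10 were called higher in SST35min and 12 in SST3h, with medians of 1.23 and 1.8. Pvalb was not called in either table (0.64 ± 0.26 and 1.56 ± 0.53), but PV markers as a list were higher too, with medians of 0.43 and 0.97 and 6 and 7 of 14 called (adjusted p = 0.306 and 0.0225 with an estimated correlation). Lhx6 and Sox6, called higher in both tables, are on both the PV and the SST list. MSN markers had medians of -0.81 and -0.93, oligodendrocyte markers of -3.17 and -2.05 and microglial markers of -2 and -1.82.

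Vascular markers were higher in bound SST nuclei too: all 15 had positive fold changes in both tables, with medians of 2.53 and 2.42, and 12 were called in SST35min and 1 in SST3h (13 in each when adjusted over the list alone). The edgeR test called 976 genes higher and 1345 lower of 15136 in SST35min, and 585 higher and 1114 lower of 15911 in SST3h. With an estimated correlation the SST list (adjusted p = 0.0401 and 0.00829) and the MSN list (0.0241 and 0.0137) stayed called in both tables, the oligodendrocyte list in SST35min (0.0171 against 0.0712 in SST3h) and the microglial list in SST3h (0.0392 against 0.101 in SST35min). The vascular list did not (adjusted p = 0.224 and 0.432). With the mouse as a block, SST3h had 4480 calls in place of 1699. Leaving out saline replicate 1, 2 or 3 of SST35min gave 652, 1547 or 1334 calls in place of 2321, and leaving out saline replicate 1-1, 4-1 or 4-2 of SST3h gave 799, 878 or 541.

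To find the early response of PV interneurons, bound PV nuclei were compared 35 min after amphetamine and saline. The immediate-early genes, transcription factors and signalling genes induced within minutes of neuronal activity, had positive fold changes in 34 of 34 members, with a median of 0.91. Fos (chromosome 12, 85473890 to 85477273) was at 8.16 ± 2.66 CPM (SD, n = 5) after amphetamine and 2.17 ± 0.36 CPM after saline, a log2 fold change of 1.93 ± 0.25 (SE) that did not pass the test (adjusted p = 0.161). The values were 1.66 for Nr4a3, 1.57 for the phosphatase gene Dusp1, 1.35 for Fosl2, 1.2 for Junb, 0.91 for Nr4a1 and 0.25 for Arc. Camera called the list higher (adjusted p = 3.28e-35, against 0.181 with an estimated correlation), and 13 members were called when adjusted over the list alone. The list's level was higher after amphetamine in the mean, 2.66 ± 0.56 against 1.9 ± 0.31 (SD, n = 5), with 4 of 5 amphetamine libraries above all saline ones (exact permutation test p = 0.0318, adjusted p = 0.212 over 40 tests).

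Over all genes, edgeR called 0 of them in bound PV35min, with 403 at an unadjusted p under 0.05 (752 expected by chance), and DESeq2 called 6. All 15 vascular markers had positive fold changes as well, with a median of 0.73, and the mitochondrially encoded genes had a median of 0.8 (adjusted p = 0.763 for both with an estimated correlation). The vascular level was 5.93 ± 1.43 after amphetamine and 5.58 ± 0.85 after saline (SD, n = 5, exact permutation test p = 0.643). Astrocyte markers were negative in 13 of 14 with a median of -0.32, and glutamatergic markers in 9 of 9 with a median of -0.22 (0.71 for both). With the vascular level as a term in the fit, 34 of 34 immediate-early members stayed positive with a median of 0.66.

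The unbound nuclei of the same mice were compared in the same way. Nr4a3, an activity-induced nuclear receptor (chromosome 4, 48045153 to 48086447), was at 57 ± 18 CPM (SD, n = 5) after amphetamine and 20.1 ± 4.02 CPM after saline, a log2 fold change of 1.52 ± 0.2 (SE). The values were 1.29 for Btg2, 1.25 for Fos, 1.16 for Fosb, 1.03 for Fosl2, 1.02 for Arc and 0.62 for the kinase gene Sik1. All 34 immediate-early members were positive with a median of 0.52, and 17 were called when adjusted over the list alone. The list's level was 2.26 ± 0.32 after amphetamine and 1.7 ± 0.17 after saline (SD, n = 5), higher in 5 of 5 libraries (exact permutation test p = 0.00794, the smallest this design allows, adjusted p = 0.212).

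Camera called the immediate-early list in unbound PV35min (adjusted p = 8.33e-59, against 0.0616 with an estimated correlation). Delayed activity-response genes had a median of 0.2 and MAP kinase feedback genes also of 0.2, with adjusted p = 0.113 and 0.396 with an estimated correlation. Vascular markers were negative in 14 of 14 with a median of -0.26, and MSN markers positive in 13 of 14 with a median of 0.1 (0.806 and 0.648). No gene passed edgeR's threshold over all genes (0 called, 537 at an unadjusted p under 0.05 where 746 were expected by chance), while DESeq2 called 20.

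In bound SST nuclei the same question gave calls at 35 min. These nuclei still held MSN RNA: the level of the MSN markers after amphetamine was 7.32 to 7.54 in bound and 8.14 to 8.65 in unbound nuclei. The 2 called genes, Nr4a3 and Fosl2, also rose in the unbound nuclei (2.33 and 1.87), so the calls cannot be assigned to SST interneurons alone. Nr4a3 was at 51.4 ± 4.28 CPM (SD, n = 3) in bound nuclei after amphetamine and 18.6 ± 1.39 CPM after saline, a log2 fold change of 1.49 ± 0.11 (SE, edgeR adjusted p = 0.0141). Fosl2 (chromosome 5, 32135801 to 32157842), an AP-1 transcription factor, rose by 1.78 ± 0.14 (edgeR adjusted p = 0.0151). Other members had fold changes of 1.61 ± 0.27 for Fos, 1.11 for Arc, 0.84 for Nr4a1 and 0.55 for Npas4, not called. Of 34 immediate-early genes 33 were positive, with a median of 0.63, and all 18 MAP kinase feedback genes were positive with a median of 0.34, among them the transcription factor gene Etv5 at 0.57.

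The immediate-early list (adjusted p = 0.0205), the MAP kinase feedback list (0.0205) and the delayed activity-response list (0.0345, median 0.24) were called in bound SST35min with an estimated correlation too. Astrocyte markers had a median of -0.57 in the same libraries, with 1 of 14 positive (adjusted p = 0.252 with an estimated correlation). Only Nr4a3 and Fosl2 were called by edgeR, against 12 genes by DESeq2. With isolation as a block, or with the vascular level as a term, 0 were called, as when any replicate other than amphetamine replicate 3 was left out, although the fold change of Nr4a3 stayed between 1.43 and 1.51.

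Unbound nuclei of the SST mice had 19 genes higher and 3 lower 35 min after amphetamine. Fos rose by 1.91 ± 0.22 (SE, n = 3), from 2.44 ± 0.51 to 9.19 ± 1.9 CPM (SD), and Fosb, Arc, a gene of synaptic plasticity, and Nr4a3 rose by 1.84 ± 0.21, 1.64 ± 0.19 and 2.33 ± 0.23 (edgeR adjusted p = 0.0143 for Fos, Fosb and Arc and 0.0214 for Nr4a3). Fosl2 had the smallest adjusted p, 0.0106, at 1.87 ± 0.17. Of the immediate-early list 32 of 34 members were positive, with a median of 0.95, and 8 were called over all genes and 23 when adjusted over the list alone. Genes lower after amphetamine were Acss3 (-0.88 ± 0.12), the oestrogen receptor gene Esr1 (-0.75 ± 0.1) and Frmpd1 (-0.65 ± 0.1).

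Of the MAP kinase feedback list 17 of 18 genes were positive (median 0.34), with Dusp1 higher by 1.21 ± 0.14 and Etv5 by 0.89 ± 0.11. Nab2, a repressor of EGR factors, rose by 0.91. The clock gene Per1 rose by 0.91 ± 0.11, and 15 of 17 circadian genes were positive, 5 of them called when adjusted over the list alone (adjusted p = 0.145 with an estimated correlation). Dio2, which activates thyroid hormone, rose by 1.13 ± 0.16, and Slco1c1, a thyroid hormone transporter, by 0.82. Homer1 (0.78), Egr1 (0.86), Per2 (0.63), Dusp5 (1.15), Junb (1.38), Npas4 (1.09) and Nr4a1 (1.26, adjusted p = 0.057) were not called.

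With an estimated correlation the immediate-early, delayed activity-response and MAP kinase feedback lists stayed called in unbound SST35min (adjusted p = 0.0127, 0.0167 and 0.028). The total of 22 calls depended on the libraries: it was 0 without saline replicate 1 or 3, 4, 10 and 110 without amphetamine replicates 1, 2 and 3, and 14 without saline replicate 2. It was 96 by DESeq2, 75 with no filter on low counts, 12 with isolation as a block and 5 with all 4 groups in 1 fit. Fold changes moved less: Fos lay between 1.75 and 1.97 in the fits that left out a replicate and lost its call. Glutamatergic markers were at 2.24 ± 0.75 after amphetamine and 1.81 ± 0.62 after saline (SD, n = 3). Markers of MSNs had a median of 0.28 with 13 of 14 positive, and cholinergic markers of -0.39 with 10 of 10 negative (adjusted p = 0.36 and 0.195 with an estimated correlation).

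**Figure D2:**
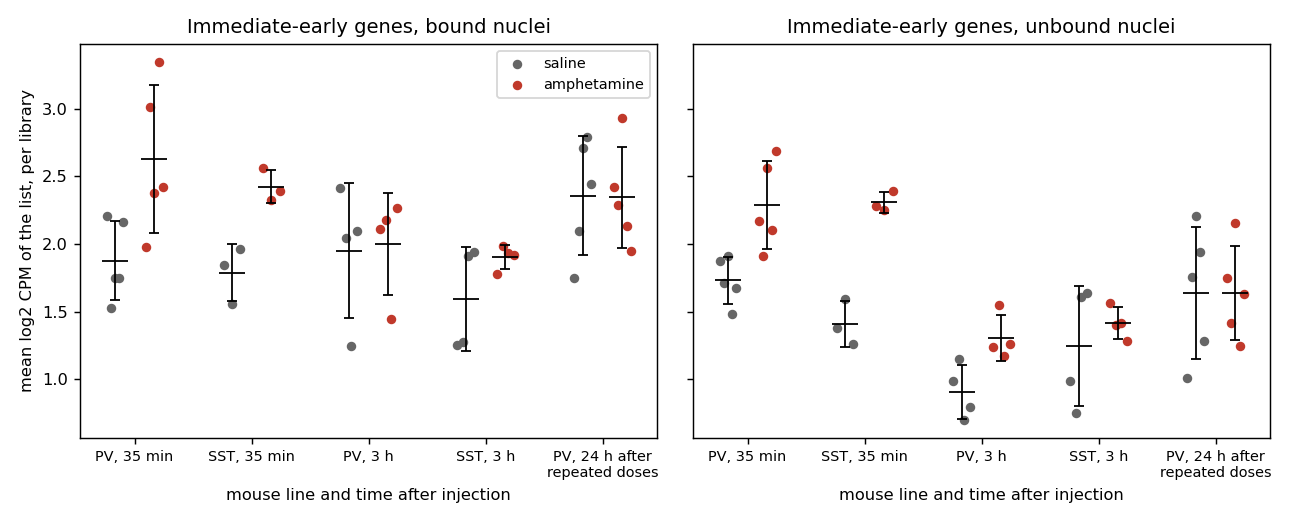
Mean log2 CPM of the immediate-early list in each library, by table and fraction, with saline in grey, amphetamine in red and bars for the mean ± SD of the group. At 35 min the amphetamine means lie above the saline means in both fractions of both crosses, and at 24 h the groups overlap.

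The unbound fractions of the 2 crosses came from different mice, so they tested the 35-min response of much the same cells independently. All 19 genes called higher in unbound SST35min had positive fold changes in unbound PV35min, 18 of them at an unadjusted p under 0.05. Across the 34 immediate-early genes the fold changes correlated with r = 0.76, and 32 were positive in both; across 14664 genes r was 0.15 (genes are not independent replicates). No call was shared in the edgeR results, since 0 genes were called in PV35min. DESeq2 called 20 and 64 genes higher and shared 15, where 0.0873 were expected (Fisher's exact test over genes, p = 1.03e-32). The 15 included Fos, Fosb, Fosl2, Arc, Btg2, Nr4a3, Sik1, Etv5 and Tiparp, and with no filter on low counts 1 gene, Btg2, was shared.

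**Figure D3:**
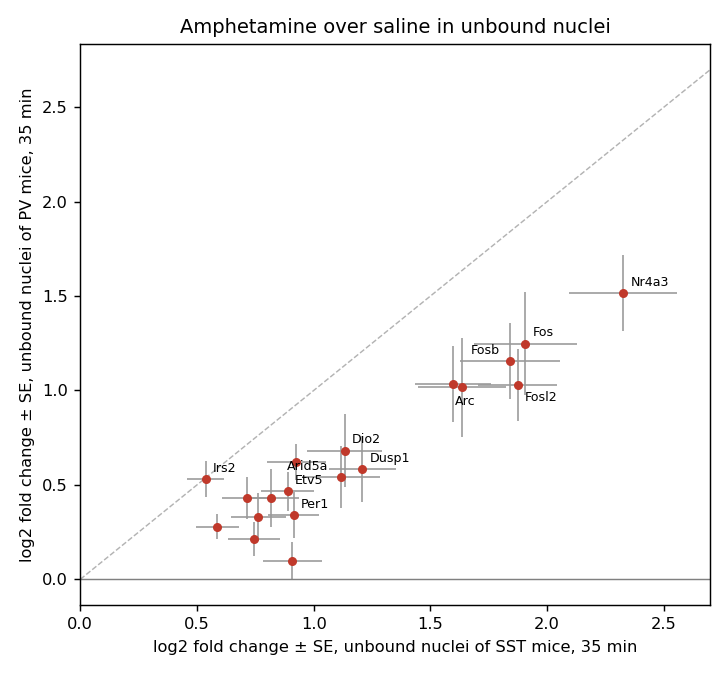
Log2 fold change after amphetamine, with SE, of the 19 genes called higher in unbound SST35min (x axis) against the same genes in unbound PV35min (y axis), with a dashed line of equal change. All 19 lie above 0 on both axes.

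At 3 h, bound PV nuclei were compared to see what followed the early response. PV markers had positive fold changes in 14 of 14 members, with a median of 0.5, and neuropeptide genes in 17 of 19, with a median of 0.46. The values were 0.63 for Lhx6, a transcription factor of the interneuron lineage, 0.55 for the secretogranin gene Scg2, 1.86 ± 0.31 (SE, n = 4) for Fosb, 1.08 for Fos and 0.86 for Npas4, but the immediate-early list as a whole had 15 of 34 members positive and a median of -0.01 (camera adjusted p = 0.208). SST markers had a median of 0.36 with 14 of 15 positive, while vascular markers had a median of -0.5 with 1 of 15 positive. Glutamatergic markers had a median of 0.48 with 9 of 10 positive. Camera called these 5 lists, but not with an estimated correlation, with adjusted p = 0.307 for PV markers, 0.0974 for neuropeptides, 0.0974 for SST markers, 0.782 for vascular markers and 0.512 for glutamatergic markers. It also called potassium channel genes (median 0.24, 22 of 24 positive), ionotropic glutamate receptor genes (0.24, 14 of 17), GABA-A receptor genes (0.23, 11 of 13) and mitochondrially encoded genes (-0.22, 0 of 10), with 0.551, 0.693, 0.693 and 0.746 with an estimated correlation. The edgeR test called 0 genes (562 at an unadjusted p under 0.05, 768 expected by chance) and DESeq2 called 7.

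Unbound nuclei of the same PV3h mice had 45 genes higher and 3 lower after amphetamine. Of the 45, 4 were on the list of glutamatergic markers, among them Slc17a7, the vesicular glutamate transporter VGLUT1 (chromosome 7, 45163949 to 45176142), was at 23.8 ± 7.9 CPM (SD, n = 4) against 3.06 ± 1.06 CPM, higher by 2.95 ± 0.31 (SE, edgeR adjusted p = 0.00854). The other 3 were Slc30a3, the synaptic zinc transporter, higher by 1.69 ± 0.23, the transcription factor gene Satb2, by 1.58 ± 0.18, and Nrn1, also on the delayed activity-response list, by 0.85 ± 0.16. Of 10 glutamatergic markers 8 were called when adjusted over the list alone and 4 over all genes, with a median of 1.43 (camera adjusted p = 4.70e-24, and 0.0114 with an estimated correlation). Neurod6 (2.53, but -1.23 with the glutamatergic level, which it is part of, as a term) and Tbr1 (1.22) were not called over all genes. Across the whole list the level was 2.67 ± 0.24 after amphetamine and 1.37 ± 0.28 after saline (SD, n = 4), with no overlap (exact permutation test p = 0.0286, the smallest this design allows, adjusted p = 0.212).

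Of the activity lists, 1 of 31 immediate-early and 2 of 33 delayed genes were called in the same libraries. They were the nuclear receptor gene Nr4a2, higher by 1.91 ± 0.2 (SE, n = 4, edgeR adjusted p = 0.0023), Nrn1 and the neuronal pentraxin gene Nptx2, higher by 0.85; Nptx1, on neither list, rose by 0.9. Runx2, a transcription factor gene, had the smallest adjusted p, 0.00156, at 0.72 ± 0.07. The values were 1 for Fos, 0.82 for Arc, 0.83 for Fosb, 0.79 for Npas4 and 0.91 for Bdnf, the neurotrophin gene, none of them called. The immediate-early list had 27 of 31 members positive, a median of 0.41 and 11 members called when adjusted over the list alone, and the delayed list a median of 0.1 (adjusted p = 0.334 and 0.458 with an estimated correlation). Robo1, an axon guidance receptor gene, fell by 0.41 ± 0.07, and Nkain3 and Dock11 by 0.3 each.

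With the glutamatergic level as a term, or with all 4 groups in 1 fit, 0 genes were called in unbound PV3h in place of 48, and Slc17a7 was at 0.69 and Nr4a2 at 1.63 in the former. That level includes Slc17a7 and did not overlap between the treatments, so the fit with it cannot part tissue content from treatment. The total was 252 by DESeq2, 88 with no filter on low counts, 29 with isolation as a block and 27 with a term for sex. It was 128, 16 or 19 without amphetamine replicate 1, 2 or 3 and 23 or 29 without saline replicate 2 or 3.

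In bound SST nuclei at 3 h, genes that glucocorticoids induce were higher after amphetamine. Of 21 such genes 19 had positive fold changes, with a median of 0.29, and 9 were called when adjusted over the list alone. The values were 1.45 ± 0.26 (SE, n = 4) for Cebpd, a transcription factor, 1.045 for Nfkbia, an inhibitor of NF-kB, 0.87 ± 0.19 for Tsc22d3, known as GILZ, and 0.28 for Fkbp5, a regulator of the glucocorticoid receptor, which was at -0.23 with isolation as a block and at -0.11 without isolation 4. Camera called the list (adjusted p = 9.03e-19, and 0.0287 with an estimated correlation). The list's level was 3.62 ± 0.12 after amphetamine and 3.07 ± 0.18 after saline (SD, n = 4), with no overlap (exact permutation test p = 0.0286, the smallest this design allows, adjusted p = 0.212). Vascular markers were positive in 15 of 15 with a median of 0.81 (adjusted p = 0.367 with an estimated correlation), and immediate-early genes had a median of 0.23 (0.317). Oligodendrocyte markers were negative in 13 of 14 with a median of -0.53 (0.584), and mitochondrially encoded genes in 9 of 10 with a median of -0.69 (0.609).

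The unbound SST nuclei at 3 h showed the same group: 19 of 21 glucocorticoid-response genes were positive, with a median of 0.55 and 13 called when adjusted over the list alone (camera adjusted p = 1.82e-24, and 0.0253 with an estimated correlation). The values were 1.06 ± 0.18 (SE, n = 4) for Pdk4, a regulator of glucose oxidation, 0.99 for Sult1a1, 0.71 for Fkbp5 (chromosome 17, 28399094 to 28517527) and 0.65 for Tsc22d3. Over all genes Fam20a rose by 0.94 ± 0.09 (edgeR adjusted p = 0.00955) and the collagen gene Col6a4 by 2.32 ± 0.28 (0.049), from 2.53 ± 0.83 to 12.7 ± 4.15 CPM (SD). Markers of MSNs had medians of -0.24 here and -0.29 in the bound nuclei, with adjusted p = 0.413 and 0.126 with an estimated correlation.

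The edgeR test called 0 genes in bound SST3h (575 at an unadjusted p under 0.05, 830 expected by chance) and 2 in unbound SST3h, and DESeq2 called 30 and 34. Isolation and treatment were unevenly spread: isolation 2 held 1 saline and 3 amphetamine mice, isolations 1 and 4 saline mice alone, and isolation 3 an amphetamine mouse alone. With isolation as a block, which leaves isolation 2 alone to compare the treatments and so 1 saline mouse, the totals were 52 and 83, and the glucocorticoid list had medians of 0.34 and 0.41, with 5 and 0 members called when adjusted over the list alone. Within isolation 2 the list's level in bound nuclei was 3.06 in the saline mouse and 3.59 in the mean of the amphetamine mice, and in unbound nuclei 3.14 and 3.57. Without isolation 4 the totals were 5 and 38. Of the 2 unbound calls, 0 were left without amphetamine replicate 2-1, 2-2 or 3-1, and 1 without amphetamine replicate 2-3 or saline replicate 1-1, 2-1, 4-1 or 4-2. Col6a4 lost its call in each fit that left out a replicate.

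The PV24h mice showed what was left 24 h after 6 days of amphetamine. The immediate-early level was the same within its spread in bound nuclei (2.4 ± 0.36 after amphetamine, 2.42 ± 0.41 after saline, SD, n = 5) and in unbound nuclei (1.59 ± 0.35 and 1.58 ± 0.49). The fold change of Fos was -0.42 in bound and -0.19 in unbound nuclei, of Arc -0.26 and 0.12, and of Fkbp5 -0.12 and -0.04, none called. In bound nuclei ionotropic glutamate receptor genes had a median of 0.34 with 14 of 17 positive, and potassium channel genes of 0.22 with 18 of 24 positive, while astrocyte markers had a median of -0.55 (adjusted p = 0.49 for each with an estimated correlation). Astrocyte markers were also at -0.22 in unbound nuclei (0.251).

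Mitochondrially encoded genes had medians of -1.46 in bound and -1.12 in unbound PV24h nuclei (adjusted p = 0.49 and 0.784 with an estimated correlation). That followed saline replicate 3-2, whose mitochondrial share was 2.13% and 1.08% of counts, and without this mouse the medians were -0.26 and -0.17. In PV24h edgeR called 0 genes in either fraction, and DESeq2 and every other alternative also called 0. At an unadjusted p under 0.05 edgeR had 401 bound and 323 unbound genes (807 and 787 expected by chance).

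Whether amphetamine acted differently on tagged and untagged nuclei was tested as a difference between effects. In PV3h 1 gene differed: Dock11, an exchange factor for Cdc42 (chromosome X, 35888832 to 36076562), went from 53.1 ± 4.4 to 70.2 ± 2.1 CPM (SD, n = 4) in bound and from 93.4 ± 2.61 to 75.6 ± 4.26 CPM in unbound nuclei, a difference of 0.72 ± 0.09 (SE, edgeR adjusted p = 0.0208). That call was lost with the mouse as a block, with no filter on low counts and when any of the 8 mice was left out, while the difference stayed between 0.67 and 0.77. Fos differed by 0.69 ± 0.38 in PV35min and -0.32 in SST35min, and Arc by -0.77 and -0.54, not called.

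The immediate-early list had median differences of 0.29 in PV35min, -0.35 in SST35min, -0.43 in PV3h, 0.16 in SST3h and -0.06 in PV24h (adjusted p = 0.936, 0.342, 0.527, 0.995 and 0.993 with an estimated correlation). The edgeR test called 0 genes in PV35min, SST35min, SST3h and PV24h, and DESeq2 also called 0. At an unadjusted p under 0.05 edgeR had 347, 285, 306 and 329 genes (786, 787, 870 and 843 expected by chance).

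Bound PV and bound SST nuclei were set against each other in the same way. At 35 min the effect on Fos was 0.33 ± 0.38 (SE) larger in bound PV than in bound SST nuclei, and that on Arc -0.85 ± 0.86. At 3 h the differences were 1.2 ± 0.46 for Fosb (edgeR adjusted p = 0.826), 0.99 for Npas4, 0.53 for Nr4a1, 0.51 for Fos, 0.21 for Arc, 0 for Egr1, -0.2 for Fkbp5 and -0.56 for Junb. Both comparisons had 0 calls by edgeR and 0 by DESeq2, so that the calls of the SST nuclei at 35 min were not shown to differ from PV nuclei. At an unadjusted p under 0.05 edgeR had 140 and 754 genes (804 and 839 expected by chance). With isolation as a block the 3-h comparison had 287 calls, which rest on a single saline mouse of SST3h, and the differences of Fos (-0.097) and Fkbp5 (0.35) were on the other side of 0. On simulated counts it recovered 68.7% of log2 changes of 2 and 29.3% of log2 changes of 1.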

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

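In this part, the tests of depth, of isolation 4 and of a response shared by both crosses, the relation of Pvalb to the vascular level, the comparison of Sun1 between bound and unbound nuclei, and the fits with the glutamatergic level as a term and without isolation 4, were chosen only after the result was seen. For depth, the first bound was a median correlation of at least 0.4 in size with the total count, and at -0.409 it was met; it was replaced by the change that depth predicts, because depth and the glutamatergic level were themselves correlated at -0.484 in the libraries used. For activity, a residual of at most 0.1 had been set in advance as evidence against it and was met; a condition on the spread of the members was added after it was seen, because the members went both ways. For the shared response, the requirement of an exact permutation test between the crosses was also added after the first values were seen, and it changed no reading. The counts of calls with the glutamatergic term and without isolation 4 were known when the bounds for the glutamatergic and isolation tests were set.

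Unbound PV3h nuclei had higher levels of 45 genes after amphetamine, 4 of them on the glutamatergic list. Depth cannot account for this: with slopes from the saline unbound libraries of the other tables, the depth difference of -0.117 (log2) predicted a median of 0.0626, against 0.852 observed. Of the 45 genes, 41 were outside the glutamatergic list, and in those 17 saline libraries their median correlation with the glutamatergic level was 0.824, against -0.034 for 10000 matched random lists. The level difference of 1.29 predicts a median of 0.81, so a candidate explanation is that the amphetamine dissections held more of a glutamatergic tissue such as the neighbouring cortex, whose most abundant marker Slc17a7 was at 23.8 against 3.06 CPM. For the immediate-early genes, activity-dependent transcription cannot be told apart from this tissue content: the residual median after the predicted change was -0.062 with an SD of 0.295 over 31 members (13 positive), the median with the level as a term in the fit was 0.63 (23 positive), and the level and the treatment did not overlap.

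Vascular genes were higher in bound than in unbound nuclei in all 5 tables, with a smallest median of 2.42. Over the 28 bound PV libraries the vascular level fell as Pvalb rose (r = -0.774, rho = -0.836, permutation p = 1.00e-05 for both, the smallest possible, adjusted 2.00e-05 over 2 relations; r = -0.746 without the 2 farthest libraries and -0.754, -0.943 and -0.842 within PV35min, PV3h and PV24h), which would follow from nuclei of another type diluting the PV nuclei. Whether those nuclei carried the reporter or were captured without it cannot be told apart, since Sun1, part of the reporter, did not follow the vascular level (r = 0.181, rho = 0.155, permutation p = 0.392 and 0.445; r = 0.154 without the 2 farthest libraries and -0.045, 0.657 and -0.326 within the tables) and was itself no higher in bound PV nuclei (-0.21, -0.07 and -0.14), so it does not track the reporter. The pulldown with an anti-GFP antibody should have removed untagged vascular nuclei, and no biological explanation was tested.

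Glucocorticoid-response genes were higher after amphetamine in both SST3h fractions. Low values in the 2 saline mice of isolation 4 do not by themselves account for the change in unbound nuclei. Without them the median there was 0.449, with 14 of 21 genes called when adjusted over the list alone. The 2 saline mice then left had unbound vascular levels of 0.085 and 0.252, against 1.509 to 2.185 after amphetamine (normalised over all libraries of the table). That fit is therefore not separated from vascular content. In isolation 4 the saline vascular levels were 2.744 and 2.899, above all amphetamine levels. In bound nuclei these mice were not low, with a mean level of 3.184 against 2.841 and 3.058 in saline mice of isolations 1 and 2. Leaving them out was therefore no test in bound nuclei, where the median was then 0.522, with 6 of 21 genes called. A response shared by both crosses at the size seen in SST3h was argued against in unbound nuclei. The PV3h mean difference was -0.023, and the exact 97.1% Wilcoxon interval of the shift ran from -0.339 to 0.368, below the SST3h difference of 0.514. The 2 mean differences were 0.537 apart (exact permutation test p = 0.0253 over 4900 regroupings). That test regrouped treatment within each table, so its null is no treatment effect in either cross, and not equal effects in both. The argument against a shared response of that size therefore rests on the interval. A smaller shared response is not excluded, and the test cannot part treatment from isolation in SST3h. For bound nuclei a shared response cannot be told apart, because the PV3h interval reached 1.49 and the exact permutation test gave p = 0.204. A response in the SST cross alone, or a difference in handling such as the isolation batches, may remain, and the medians with isolation as a block, 0.338 and 0.409, rest on isolation 2 alone, with 1 saline mouse, and so do not settle the latter. In bound SST3h nuclei the vascular level was 5.1 ± 0.61 after amphetamine and 4.05 ± 1.33 after saline (SD, n = 4, exact permutation test p = 0.171). The change of the list there is therefore not separated from vascular content.

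The remaining flags are values of libraries that stood apart from the rest of their group. Of 160 groups tested, 11 were flagged, where chance alone flags about 8. In bound PV35min nuclei Sst was at 26.5 CPM in amphetamine replicate 1 (others 10.3 to 13.1) and at 33.8 CPM in saline replicate 4 (others 9.27 to 10.1). The mitochondrial share of unbound PV35min amphetamine replicate 2 was 0.343% (others 0.054 to 0.102%). In bound PV3h nuclei the vascular level of amphetamine replicate 3 was 5.09 (others 6.58 to 6.81), and Fos was at 3.67 CPM in amphetamine replicate 4 (others 2.32 to 2.54). Fkbp5 was at 61.1 CPM in unbound PV3h amphetamine replicate 4 (others 38.7 to 39.1). In bound SST3h nuclei Pvalb was at 2.83 CPM in amphetamine replicate 2-2 (others 5.29 to 5.63) and at 16 CPM in saline replicate 2-1 (others 3.66 to 4.94). The glucocorticoid level of unbound SST3h saline replicate 4-1 was 2.93 (others 3.23 to 3.25), here normalised with all libraries of its table. In PV24h saline replicate 3-2 the mitochondrial share was 2.13% of bound counts (others 0.203 to 0.279%) and 1.08% of unbound counts (others 0.153 to 0.262%). Dock11 was flagged for the difference of 0.72 between its bound and unbound amphetamine effects in PV3h.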

How the results depend on the processing

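The vascular and glutamatergic terms and the fits without isolation 4 or the high-mitochondrial mouse were chosen after seeing the data. Over 3857 values of 308 named gene results, 3423 kept their side of the threshold and direction, 222 lost the call and 67 gained one. Another 143, of genes past the threshold in neither fit, changed direction: 108 of them without a replicate, 14 with a block and 8 without isolation 4. Among those the text gives, Fos at 24 h went from -0.42 to 0.12 in bound and from -0.19 to 0.39 in unbound nuclei without saline replicate 3-1. Arc in bound PV35min went from 0.25 to -0.12 without amphetamine replicate 1, its difference between fractions there from -0.77 to 0.15 without saline replicate 4, and Sst in bound against unbound PV3h from -0.19 to 0.11 without saline replicate 1. The other 2 values were of genes called in unbound PV3h: with the glutamatergic term Mas1 went from 1.47 to -0.5 and Prss12 from 1.46 to -0.29 (both named after their values were seen). In the amphetamine-treated mice 150 of 23105 genes called in bound against unbound nuclei had the opposite sign. Of 147 calls among the named genes DESeq2 kept 147 and gained 34, RLE kept 145, and fits with no filter kept 141 and gained 9. With RLE every count of calls stayed within 1.5 times the first. In bound against unbound PV24h, no filter on low counts moved the median of all genes from 0.002 to 0.121.

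By DESeq2 the amphetamine calls were 6 in bound and 20 in unbound PV35min, 12 and 96 in SST35min, 7 and 252 in PV3h and 30 and 34 in SST3h; bound against unbound SST3h had 2750 and the shared calls at 35 min were 15. With no filter they were 1 in unbound PV35min, 75 in unbound SST35min and 88 in unbound PV3h, 0 for the PV3h difference and 1 for the shared calls. With the mouse or isolation as a block, bound against unbound SST3h had 4480, unbound PV35min 1, SST35min 0 bound and 12 unbound, unbound PV3h 29, SST3h 52 bound and 83 unbound, the PV3h difference 0 and the 3-h difference between crosses 287. In SST3h the isolation block leaves 1 saline mouse against 3 amphetamine mice, so its 52, 83 and 287 assume that this mouse varies like the others. All 4 groups in 1 fit gave 4 in bound PV35min, 5 in unbound SST35min, 0 in unbound PV3h and 3 bound and 1 unbound in SST3h. The sex term gave 27 and the glutamatergic term 0 in unbound PV3h, the vascular term 0 in bound SST35min, isolation 4 left out 5 bound and 38 unbound in SST3h, and the amphetamine-treated mice 5133 in bound against unbound SST3h. The cause of these shifts was not tested, except that a fit without isolation 4 has fewer samples and one with no filter tests more genes. Of 500 list tests camera called 213 at the preset correlation, 24 with an estimated correlation, all among the 213, and fry 86.

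Leaving out each replicate in turn gave 652 to 1547 calls for bound against unbound nuclei in SST35min, 3504 to 7661 in PV3h and 541 to 1350 in SST3h, 6153 to 7110 in PV35min and 3893 to 5191 in PV24h. For amphetamine it gave 0 to 1 in bound and 0 to 1 in unbound PV35min, 0 to 2 in bound and 0 to 110 in unbound SST35min, 16 to 128 in unbound PV3h, 0 to 2 in unbound SST3h and 0 for the PV3h difference and the other comparisons. Depth limits the low genes: Fos, at 1.12 to 9.91 CPM in the group means, is a gene of few counts in these nuclear libraries.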

Other observations

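The list tests and the other splits in this part were planned, while the correlation of all fold changes between the crosses was chosen after the gene results were seen.

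Bound and unbound nuclei differed in more than the markers described above. Genes of dopamine and cAMP signalling, the core of MSN physiology, were lower in bound nuclei of all 5 tables, with medians of -1.84, -0.67, -1.1, -0.62 and -0.8 in PV35min, SST35min, PV3h, SST3h and PV24h (adjusted p = 0.0282, 0.0226, 0.0966, 0.0428 and 0.482 with an estimated correlation). Markers of D1 MSNs had medians of -0.9, -0.53, -0.67, -0.26 and -0.85 and those of D2 MSNs of -1.89, -0.56, -0.96, -0.55 and -0.77, where 0 of these list tests passed with an estimated correlation (smallest adjusted p = 0.0592). Oligodendrocyte precursor markers were at -1.82, -1.81, -0.98, -1.24 and -0.77, in the same order (adjusted p = 0.0592, 0.0241, 0.222, 0.0682 and 0.498 with an estimated correlation). Microglial markers were at -1.75, -0.78 and -0.57 in the PV tables, in that order of time (0.121, 0.409 and 0.498).

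The median of neuropeptide genes was -1.49, -0.88 and -0.74 in bound PV nuclei of the 3 times and 0.29 in SST3h (adjusted p = 0.029 with an estimated correlation, against 0.289, 0.361 and 0.498 in the PV tables), while in SST35min the median was -0.09, the mean 0.39 and the test upward (0.306). The difference between the crosses was not tested. Circadian clock genes had medians of -0.26, -0.16, 0.04, -0.34 and 0.14 in the 5 tables in the order above (adjusted p = 0.501, 0.273, 0.923, 0.0137 and 0.89 with an estimated correlation), so that SST3h alone passed; in PV3h and PV24h the test pointed down against a positive median and mean. GABA-A receptor genes had medians of -0.89, -0.27, -1.27, -0.28 and -0.81 and ionotropic glutamate receptor genes of -0.25, -0.04, -0.85, -0.2 and -0.69. Potassium channel genes were at -0.19, -0.23, -0.6, -0.29 and -0.62, cholinergic interneuron markers at -0.4, -0.41, -0.76, 0.14 and -0.71, and none of the lists in this and the previous sentence passed with an estimated correlation. Mean and median disagreed for the cholinergic list in SST3h (mean -0.2, test downward), and the potassium channel test in PV35min was upward at a mean of -0.03. Astrocyte markers were lower in the SST tables (-1.35 and -0.98, adjusted p = 0.151 and 0.157 with an estimated correlation) and had medians of -0.33, 0.4 and 0.65 in PV35min, PV3h and PV24h, of which camera called PV24h alone (0.498 with an estimated correlation). In PV35min the mean of the astrocyte list was 0.28 and its test upward, against the sign of the median. Chromatin regulators (-0.01, 0.03, -0.17, -0.11 and -0.11) and heat-shock genes (-0.07, -0.11, 0.35, 0.13 and 0.21) were not called by camera in any of these comparisons; the heat-shock mean in PV35min was 0.42, with an upward test. Immediate-early genes had medians of 0.05, 0.42, 1.24, 0.19 and 0.73 in the same order of tables, glucocorticoid-response genes of 0.1, -0.15, 0.65, -0.12 and 0.68, mitochondrially encoded genes of -1.18, -1.62, 0.37, -0.72 and 0.55, and glutamatergic markers of -1.7, -1.06, -0.07, -1.43 and -0.2. None of these 4 lists passed with an estimated correlation (smallest adjusted p = 0.116), and the immediate-early test in PV35min pointed down against a positive median and mean. Among the largest increases in bound PV nuclei were also Tmem212 (4.83 ± 0.88 in PV35min and 6.9 ± 0.53 in PV24h, SE, n = 5), Ccdc153 (6.04 ± 0.59 in PV24h) and Myoc (6.13 ± 0.54 and 5.96 ± 0.63).

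Camera at the preset correlation called more lists after amphetamine than those described above, none of which passed with an estimated correlation (adjusted p in brackets). Bound PV35min had delayed activity-response genes at a median of 0.19 (0.27), MAP kinase feedback genes at 0.22 (0.481), neuropeptides at 0.19 (0.71), potassium channels at -0.1 (0.763) and ionotropic glutamate receptors at -0.13 (0.71). Unbound PV35min had circadian genes at 0.05, dopamine and cAMP genes at 0.04 and chromatin regulators at 0.03 (0.648 for each). Bound SST35min had neuropeptides at 0.35 (0.337), GABA-A receptors at -0.125 (0.337), and dopamine and cAMP genes at 0.08 and MSN markers at 0.11 (0.368 for both). Unbound SST35min had glucocorticoid-response genes at 0.14, GABA-A receptors at -0.15 and dopamine and cAMP genes at 0.14 (0.36 for each), chromatin regulators at 0.06 (0.617), PV markers at -0.075 (0.231) and SST markers at -0.23 (0.195).

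Unbound PV3h had MAP kinase feedback genes at 0.18 (0.334), heat-shock genes at 0.17 (0.662), neuropeptides at 0.19 (0.545), GABA-A receptors at -0.085 and cholinergic markers at -0.29 (0.349 for both), MSN markers at -0.11 (0.686), D2 markers at -0.14 (0.482) and oligodendrocyte markers at -0.145 (0.458). Bound SST3h had delayed genes at 0.055 (0.144), MAP kinase feedback genes at 0.11, potassium channels at -0.13, ionotropic glutamate receptors at -0.13 and oligodendrocyte precursor markers at -0.26 (0.382 for each). It also had circadian genes at -0.065 (0.135), dopamine and cAMP genes at -0.14 (0.151), D2 markers at -0.19 (0.123), astrocyte markers at -0.31 (0.609) and microglial markers at 0.24 (0.582). Unbound SST3h had immediate-early genes at 0.04 (0.864), mitochondrially encoded genes at -0.345 (0.446), and delayed genes at 0.06, circadian genes at -0.08, dopamine and cAMP genes at -0.09, D2 markers at -0.22 and microglial markers at -0.23 (0.413 for each). Bound PV24h had chromatin regulators at 0.06 (0.49), PV markers at 0.285 (0.673), cholinergic markers at -0.4 (0.133) and microglial markers at -0.39 (0.542), and unbound PV24h heat-shock genes at -0.145 and cholinergic markers at -0.2 (0.784 for both).

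For the difference between the bound and the unbound effect no list passed with an estimated correlation. Among cell types called at the preset correlation were vascular markers in PV35min (1.01), SST3h (0.77) and PV24h (0.23), with adjusted p = 0.936, 0.995 and 0.729 with an estimated correlation. Astrocyte markers were called in PV35min (-0.25), SST35min (-0.53), SST3h (-0.32) and PV24h (-0.42), with 0.936, 0.342, 0.929 and 0.729, and glutamatergic markers in PV3h (-0.92, 0.453).

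After amphetamine, glucocorticoid-response genes had medians of 0.39 in bound and 0.14 in unbound PV35min (adjusted p = 0.763 and 0.648 with an estimated correlation), and heat-shock genes of -0.24 in bound PV24h (0.49). The fold changes of all genes correlated across the crosses at r = 0.31 in bound nuclei at 35 min, and at -0.07 in unbound and -0.17 in bound nuclei at 3 h (across genes, which are not independent replicates).

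Other splits of the same libraries were fitted to see whether chance could give as many calls. For bound against unbound nuclei the splits regrouped single libraries and so ignored the pairs by mouse. Within that limit they argued against chance in PV35min (7611 calls, highest other split 0, 1 of 100 splits as large, the real one), PV24h (5396, 0, 1 of 100), PV3h (6078, 0, 1 of 35) and SST3h (1699, 1020, 1 of 35). The split with 1020 calls set mice 1-1 and 2-1 against the rest, which follows isolation, and the blocked count was 4480. SST35min has too few splits to tell (2321, highest other 0, 1 of 10). In its amphetamine-treated mice, which are other animals, 1516 of the 2321 genes were called again in the same direction and 4 had the opposite sign. That argues against chance for these calls. For amphetamine, the splits argued against chance in unbound PV3h (48, highest other 5, 1 of 35). That share is the smallest this design allows and was not adjusted over the comparisons. The splits there cannot part treatment from a difference in tissue content between the 2 groups of mice. In unbound SST3h the real split was the largest by a single call (2, highest other 1, 1 of 35), which is too small a margin to exclude chance. That other split set isolation 2 against the rest, and the splits cannot part treatment from isolation, with which it is unevenly spread; the blocked count was 83, with 1 of the 2 genes among them, from 1 saline against 3 amphetamine mice. SST35min again has too few splits, with 2 bound calls (highest other 5, 2 of 10) and 22 unbound calls (highest other 3, 1 of 10). The 19 unbound genes called higher were all positive in unbound PV35min, from other mice, 18 of them at an unadjusted edgeR p under 0.05. That argues against chance for those 19 genes. Where the real count was 0, every split was at least as large, so the splits test nothing there: 100 of 100 in both fractions of PV35min and PV24h and 35 of 35 in bound PV3h and SST3h, with highest others of 1589 and 262 in bound and unbound PV35min, 1 and 3 in PV24h, 1689 in bound PV3h and 2 in bound SST3h. The large counts of 1589, 1689 and 262 point to a structure of the samples other than treatment. The split with 1589 calls set the bound PV35min libraries with vascular levels of 4.21 to 5.67 against those with 6.18 to 7.55. The split with 1689 calls put the lowest vascular levels of bound PV3h, 5.09 and 5.19, in the same group. For the differences between effects, chance cannot be excluded for the 1 call in PV3h (3 of 35 splits, highest other 618, again a structure of the samples). Counts of 0, which every split reaches and which are therefore no test, were those of PV35min (100 of 100, highest other 350), SST35min (10 of 10, 0), SST3h (35 of 35, 0), PV24h (100 of 100, 0) and the crosses at 35 min (100 of 100, 0) and 3 h (100 of 100, 3).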
